A study of Mus musculus with 28 samples.

How the data were processed

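Liver RNA of 28 mice in 5 diet groups was hybridised to 1 array per liver, on a whole mouse genome array with 45018 spots, of which 43379 held 41174 probes that were not controls. Per the file headers, the signal intensity of each spot was extracted with Agilent Feature Extraction from 1-colour (Cy3) scans. Its processed intensity was background-subtracted, detrended within the array, and replaced by a surrogate where it fell under the noise. The deposited value table holds 1 score per probe and array. Each array's scores have a mean of 0 and an SD of 1 and follow the log of that array's processed signal, so they were used as an alternative only, after multiplication by 3.21 to bring them to a log2 scale. Groups and replicate numbers were taken from the labels. Slide and scan day were taken from the file headers.

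The processed intensities were put on the log2 scale, spots of the same probe were averaged, and the 75th percentile over non-control probes was subtracted from each array. Probes were kept if the scanner software called them well above background on at least 5 arrays, which left 32095 probes. Probe names were updated with a table of RefSeq accessions and symbols: 25097 probes matched by accession, 6333 by symbol and 1640 by a single synonym, and 8104 kept the name of the array design. For 7088 genes with more than 1 kept probe, the probe with the highest mean over all 28 arrays stood for the gene, so that 21862 genes were tested. Coordinates are those of build mm9 in the array files.

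All 28 arrays were fitted in 1 linear model with limma 3.58.1 (lmFit, contrasts.fit and eBayes) in R 4.3.3. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes passed at an adjusted p under 0.05. Errors of differences are standard errors from this model. Each array comes from a separate mouse. Samples that share a replicate number were compared by the correlation of their deviations from the group means, and numbers were taken to pair the livers of a comparison where every correlation was over 0.1. That held for HFD and SD (5 pairs, 0.217 to 0.698), from the values and not from the labels, and for none of the other 9 pairs of groups. Replicate numbers follow the order of the slides, and replicates 1 and 2 of HFD and SD share a slide. The comparisons were HFD with SD, each supplemented group with HFD, HQ with HR, HQR with HQ, with HR and with their mean, and each supplemented group with SD. In each, 33 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists, after 186 genes with a missing value had been left out. List tests with a block were run with camera at the preset correlation only. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. That rule took the 5 largest rises and falls past the threshold (or the smallest p where fewer passed), up to 3 members of each called list, and a fixed set of genes known from fatty liver and from the compounds. Genes outside it are named too, such as further changed genes, list members that passed when adjusted over the list alone, and genes used in later tests. Pck1 of that set was not measured.

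Where no array of the dimmer group was well above background, the fold is given as at least the ratio of the brighter group's mean to the higher, on each array, of the lowest well-above-background signal and the gene's own signal. This ratio takes no account of the spread between livers. Where the gene's own signal was the higher on every array, the ratio equals the fitted fold and is no lower limit. The relation between comparisons that share arrays was computed with the shared HFD arrays split into 2 sets of 3, over all such splits, and set beside 100 simulations of unchanged groups made by permuting residuals. Shares of variance explained were compared with 10000 permutations. Counts were compared with 100 splits of the same arrays into groups of the same sizes.

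Alternatives were quantile normalization, scaling to the array median, normexp background correction with an offset of 50, no filter and a strict filter on dim probes, the mean of all probes of a gene, the deposited value table, a fit of the compared arrays alone, an intensity trend with robust estimation, array weights, a minimum fold of 1.5, slide, scan day or replicate number as a block, and leaving out each array in turn. Slide as a random block, quantile normalization with slide as a block, and leaving out slide 8 were added after the data had been seen, as were contrasts of the 4 high fat groups with SD and of the 3 supplemented groups with HFD, and overlaps of calls with the shared arrays split.

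The pipeline was tested on simulated data made from the same arrays. Of 100 genes changed 2-fold, 48 were called in HFD against SD, 32 in HQ, 53 in HR and 49 in HQR against HFD, and of 100 changed 4-fold, 90, 81, 91 and 90 were called, with 0 to 2 calls among unchanged genes. These counts rest on 1 shuffle of the arrays per comparison. In the 100 simulations of unchanged groups, genes were called in 1, 3, 2 and 2 simulations for the same comparisons. The highest counts there were 2, 5342, 1851 and 3245, so false calls were rare but could be many at once. When the cell cycle list alone was shifted, camera with the preset correlation called it and 11 or 12 other lists too, so its calls are given with the estimated correlation beside them. Tables and figures were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.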

Results

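Gene expression was measured in the livers of 28 male C57/6J mice, with 1 array per liver. The mice entered the experiment at 7 weeks of age and were 33 weeks old after 26 weeks on their diets. A standard diet (SD) was given to 5 of the mice and a high fat diet (HFD) to 6. The high fat diet was supplemented with 0.4% quercetin, a flavonol, in 5 mice (HQ), with 0.4% resveratrol, a stilbene, in 6 mice (HR), and with 0.2% of each in 6 mice (HQR). Per the labels, 2 of the 30 RNA samples of the experiment were degraded and were not put on arrays. Between 59.4% and 82.1% of the probes of an array were well above background, and the 75th percentile of the processed signal lay between 180 and 574. Replicate spots of a probe had a median coefficient of variation of 3.90% to 6.89%, and no spot was saturated. After removal of dim probes, 21862 genes were tested. Expression is given below as log2 signal relative to the 75th percentile of the same array, and the number of arrays limits the precision of every difference.

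The 28 arrays lay on 9 slides that were scanned on 4 days, and the slides accounted for more of the variation than the diets did. The first principal component held 42.1% of the variance, and slide explained a share of 0.739 of it (0.295 expected by chance, permutation p = 0.0009). Group explained a share of 0.0364 of that component (0.148 expected by chance, permutation p = 0.919). For the second component, with 11.1% of the variance, the share was 0.898 for slide (permutation p = 1e-04, the smallest that the permutations could give), 0.691 for scan day and 0.0983 for group. The median correlation between arrays, across genes, was 0.970 within groups, 0.970 between groups and 0.976 within slides. The 3 arrays of slide 8 (HFD replicate 5, HR replicate 6 and HQR replicate 4) had at least 79.4% of their probes well above background, against at most 74.3% on all other slides. Because slides other than slide 4 held arrays of several groups, differences were also fitted with slide as a block, and calls of named genes that this ended are given below. Slide 4 held HQ replicate 3 alone, so the HQ values with slide as a block rest on the other HQ livers.

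**Figure D1:**
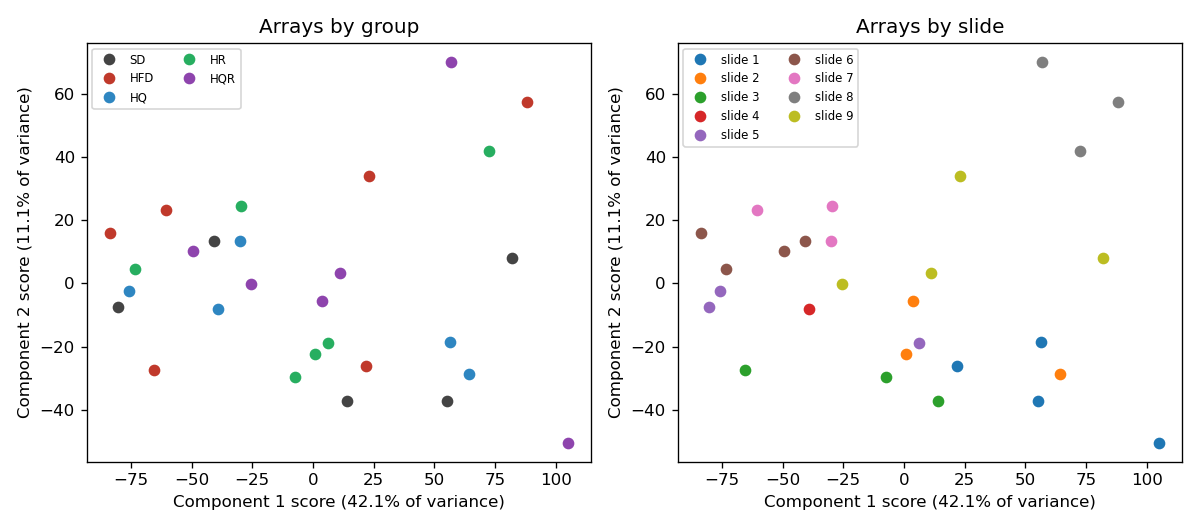
Scores of the 28 arrays on the first 2 principal components (42.1% and 11.1% of the variance; no unit), coloured by diet group in one panel and by slide in the other; each point is 1 array. Slide explained a share of 0.739 of the first component and group a share of 0.0364.

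The first comparison, HFD against SD, asked what 26 weeks of high fat feeding changed in the liver. Cfd, which encodes the serine protease adipsin of the alternative complement pathway, rose from 0.34 ± 1.58 (SD, n = 5) to 5.78 ± 0.41 (SD, n = 6), a 43.5-fold difference. Cidea, which encodes a lipid droplet protein, rose 57.6-fold, from -1.11 ± 1.51 to 4.74 ± 1.04, and the related Cidec rose 9.04-fold. The cytochrome P450 genes Cyp2b9 and Cyp2b13, which are more highly expressed in female than in male mouse liver, rose 62.4-fold and 28.2-fold. Hao2, which encodes a peroxisomal hydroxy acid oxidase (Hao3 on the array), was well above background in 6 of 6 HFD livers and in 0 of 5 SD livers, and was at least 8.48-fold higher in HFD. This bound leaves out the spread between livers. In the other direction, Asns, the gene of asparagine synthetase, fell by 3.16 ± 0.52 (SE) on the log2 scale, and Moxd1, which encodes a monooxygenase, fell by 5.19 ± 0.80, a value that is not exact because 1 of 6 HFD arrays was well above background.

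In this comparison 25 genes passed an adjusted p of 0.05, of which 15 rose and 10 fell, and 1350 genes had an unadjusted p under 0.05 where 1093 would be expected by chance. The adjusted p was 1.42e-05 for Cfd, 3.29e-05 for Cyp2b9, 0.000118 for Hao2, 0.000137 for Cyp2b13 and 0.000336 for Cidea. It was 0.00155 for Moxd1, 0.00359 for Asns, 0.0132 for Cidec and 0.017 for Pparg, the gene of the adipogenic transcription factor PPARgamma, which rose 2.06-fold. Tff3, which encodes a trefoil peptide, fell by 1.93 ± 0.30 (adjusted p = 0.0018), and Enho, which encodes the secreted peptide adropin, fell by 1.65 ± 0.25 (adjusted p = 0.00107). Fam222a fell by 1.78 ± 0.34 (adjusted p = 0.022). All 6 HFD livers differed from the SD mean in the stated direction for each of these 12 genes. In the coordinates of mouse build mm9 that the array files give, the probes lie on chromosome 10 from 79355302 to 79355361 for Cfd, on chromosome 18 from 67527351 to 67527410 for Cidea, and on chromosome 6 from 113374693 to 113374752 for Cidec. They lie on chromosome 7 from 26995607 to 26995666 for Cyp2b9 and from 26873757 to 26880713 for Cyp2b13, on chromosome 3 from 98678664 to 98678723 for Hao2, on chromosome 6 from 7625194 to 7625253 for Asns and on chromosome 10 from 24022208 to 24022266 for Moxd1. Of 11 further genes that changed, which the rule for named genes did not pick in this comparison, Vldlr (1.47), Aatk (1.40), Sema5b (1.65), Adam11 (1.52), Tpm2 (1.66) and Olfr701 (1.74) rose, and Slc1a5 (-1.09), H2-Q1 (-1.62), Hunk (-1.32), Fst (-1.49) and Appl1 (-0.82) fell.

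Differences within the 4 slides that held both groups were 4.54 to 7.62 for Cfd, 3.60 to 9.10 for Cidea, 4.72 to 7.29 for Cyp2b9, 3.99 to 5.63 for Cyp2b13, -8.66 to -0.35 for Moxd1 and -5.07 to -0.29 for Asns. With slide as a block, 33 genes passed, 19 of them among the 25, and the adjusted p was 8.39e-07 for Cfd. In that fit 2505 genes had an unadjusted p under 0.05, against 1350 without the block. Fam222a (0.0781), Adam11 (0.0792), Tpm2 (0.0533), Olfr701 (0.0676), Fst (0.0541) and Appl1 (0.0871) were then not past the threshold. Normexp background correction ended the call of Hao2 (log2 difference 0.38, adjusted p = 0.907). Tff3 (log2 difference -1.33) and Pparg (adjusted p = 0.158) were then not past the threshold either, and Pparg (0.412) and Fam222a (0.132) were not with scaling to the array median. A fit of the HFD and SD arrays alone left 10 genes past the threshold, and Moxd1 (adjusted p = 0.165), Asns (0.125), Cidec (0.266), Pparg (0.130), Tff3 (0.154), Enho (0.0717) and Fam222a (0.141) were then no longer past it. Array weights ended the call of Moxd1 (adjusted p = 0.061). Without HFD replicate 3 the count was 15 and Cidec, Pparg and Fam222a did not pass. Cidec also depended on SD replicate 5, Pparg on SD replicates 1, 3 and 5, and Fam222a on SD replicates 3, 4 and 5 and HFD replicates 1, 4 and 6.

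**Figure D2:**
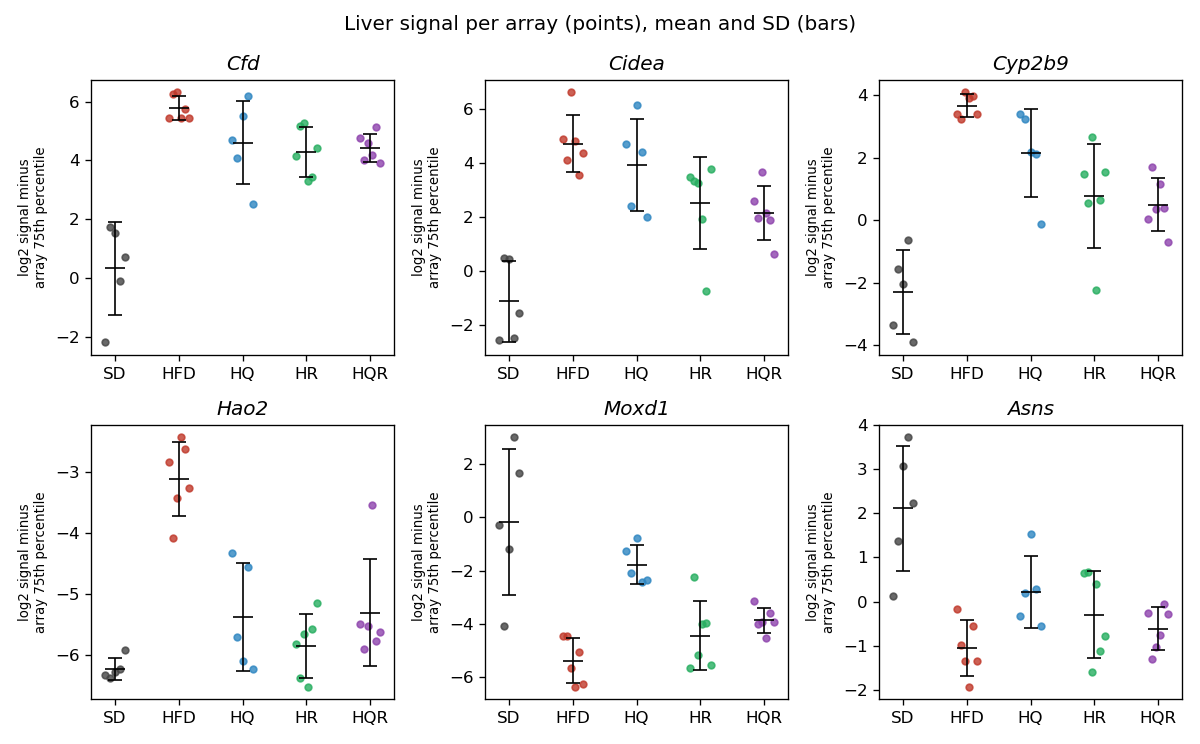
Log2 signal relative to the array's 75th percentile for Cfd, Cidea, Cyp2b9, Hao2, Moxd1 and Asns in each of the 28 livers by diet group; each point is 1 array and bars are the mean with the SD. Cfd averaged 5.78 in HFD livers and 0.34 in SD livers.

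Of the lipid droplet and PPARgamma target genes, 3 of 23 rose (Cidea, Cidec and Pparg) and 20 did not pass, while 6 rose when adjusted over the list alone, with Mogat1 (1.23), Plin4 (1.76) and Cd36 (1.64) added. Camera with a preset correlation called this list higher (median 0.09, mean 0.60), and the adjusted p = 0.802 with an estimated correlation. The genes of cholesterol synthesis and uptake were called lower, with a median of -0.33 and 21 of 23 members below 0 (adjusted p = 0.802 with an estimated correlation). No member of that list passed over all genes and 2 fell when adjusted over the list alone: Sqle, which encodes squalene epoxidase, at -1.90 ± 0.41, and Cyp51, which encodes lanosterol demethylase, at -1.28 ± 0.41. With slide as a block the list's adjusted p was 0.000498 by camera with the preset correlation, and the block was not run with an estimated one. The female-biased genes were called higher, although their median was -0.06 and their mean 0.59, and 3 of 23 members rose (Cyp2b9, Cyp2b13 and Hao2). When adjusted over the list alone, 4 of them rose and 1 fell, with Cyp26a1 (2.81), which encodes a retinoic acid hydroxylase, and the repressor gene Cux2 (-1.62) added (adjusted p = 0.802 with an estimated correlation). Lipoprotein genes were called lower with 14 of 23 members below 0, a median of -0.23 and 2 members that fell when adjusted over the list alone, Apom at -1.05 and Apoa1 at -0.63 (adjusted p = 0.834 with an estimated correlation). Acute phase genes were called lower with 21 of 26 below 0 and a median of -0.23 (adjusted p = 0.834 with an estimated correlation), and cell cycle genes higher with 16 of 25 above 0 and a median of 0.16 (adjusted p = 0.802 with an estimated correlation). Medians of the other 27 lists lay between -0.37 for Kupffer cell markers, with 8 of 10 below 0, and 0.30 for erythrocyte genes, and camera called none of them. Adipocyte markers had a median of -0.27, and Cfd was the 1 of 9 that rose. Genes often followed in fatty liver did not pass: Cd36, a fatty acid transporter gene, differed by 1.64 ± 0.54 (adjusted p = 0.487), Srebf1 by 1.22, Scd1 by 0.62, Fasn by 0.14, Cyp7a1, the gene of the rate-limiting enzyme of bile acid synthesis, by -0.52, and Fgf21 by -0.99. The slide block ended the calls of lipoprotein genes (adjusted p = 0.583), female-biased genes (0.0536) and acute phase genes (0.332). With replicate number as a block, the calls of lipoprotein genes (adjusted p = 0.112), female-biased genes (0.0540) and acute phase genes (0.170) were lost. As many lists as the 6 called here were called in 89 of 100 splits of the same arrays.

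Quercetin was compared with the high fat diet alone to ask what the compound changed in livers on that diet. No gene passed limma's adjusted p of 0.05 in HQ against HFD, and 465 genes had an unadjusted p under 0.05 where 1093 would be expected by chance. With fewer small p-values than chance gives, the lack of calls does not show a lack of effect. The smallest adjusted p, 0.0787, belonged to Hao2, which was well above background in 0 of 5 HQ livers and 6 of 6 HFD livers. It was 4.85-fold lower in HQ, a value that equals the fitted fold and is no lower limit. Single livers came close to each other, with Hao2 at -4.34 in HQ replicate 1 and -4.09 in HFD replicate 2. Moxd1 was -1.78 ± 0.72 (SD, n = 5) in HQ and -5.37 ± 0.85 (SD, n = 6) in HFD (adjusted p = 1.00), where 1 of 6 arrays was well above background, so that no exact difference is given. Cyp2b10, which encodes a P450 that responds to the receptor CAR, was well above background in 0 of 5 HQ livers and was at least 4.50-fold lower, and Ndufs3, a gene of respiratory complex I, differed by -0.59 ± 0.15. Neither Cyp2b10 nor Ndufs3 passed. With normexp background correction Hao2 and Cyp2b10 changed sign, to 0.18 (adjusted p = 0.754) and 0.28 (adjusted p = 0.617). That correction also shifted the median of all genes in this comparison to 0.25, so these signs do not show a rise over other genes. Within the 2 slides that held both groups the differences were -3.82 to -1.50 for Hao2, which are not exact because 0 of 5 HQ livers were well above background. With slide as a block 0 genes passed, the adjusted p of Hao2 was 0.384, and 962 genes had an unadjusted p under 0.05. Without HFD replicate 2, HQ replicate 1 or HQ replicate 4, 1 gene passed, Hao2 each time.

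Camera called 8 of 33 lists in HQ against HFD, and none of their members passed over all genes. Genes of stellate cells and extracellular matrix were called higher, with 28 of 29 members above 0 and a median of 0.23, such as Loxl2 (0.56) and Mmp2 (0.59), and the adjusted p = 0.182 with an estimated correlation. Interferon response genes were called higher, with 26 of 28 above 0 and a median of 0.27, such as Oas1a (0.50), Gbp3 (0.51) and Stat2 (0.39), and the adjusted p = 0.182 with an estimated correlation. Calls lost with slide as a block were those of interferon response (adjusted p = 0.250), sinusoidal endothelium (0.0681) and macrophage genes (0.731). Markers of sinusoidal endothelium were called higher, with 14 of 14 above 0 and a median of 0.35 (adjusted p = 0.354 with an estimated correlation), and macrophage genes with 20 of 26 above 0 and a median of 0.15 (adjusted p = 0.888 with an estimated correlation). P450 genes of drug metabolism were called lower, with 28 of 33 below 0 and a median of -0.24 (adjusted p = 0.266 with an estimated correlation), as were female-biased genes, with 16 of 23 below 0 and a median of -0.16 (adjusted p = 0.266 with an estimated correlation). When adjusted over the list alone, 1 P450 gene and 2 female-biased genes fell, Cyp2b10 in both lists and Hao2 in the second. Oxidative phosphorylation genes were called lower with 43 of 50 below 0 and a median of -0.20 (adjusted p = 0.888 with an estimated correlation), with Ndufs3 the 1 that fell when adjusted over the list alone, and NRF2 targets with 23 of 32 below 0 and a median of -0.20 (adjusted p = 0.888 with an estimated correlation). As many lists were called in 83 of 100 splits of the arrays.

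Resveratrol was compared with the high fat diet alone in the same way. Hao2 fell in HR livers to -5.86 ± 0.52 (SD, n = 6) from -3.11 ± 0.61 (SD, n = 6) in HFD livers. It was well above background in 0 of 6 HR livers, and was 6.70-fold lower, in 6 of 6 HR livers (adjusted p = 0.00159, and 0.00106 with slide as a block). That value equals the fitted fold and is no lower limit. Olfr701, an olfactory receptor gene on chromosome 7 from 113963834 to 113963893, fell by 1.98 ± 0.34 (SE) in 6 of 6 HR livers (adjusted p = 0.0435) and was well above background in 4 of them. These were the 2 genes that passed, and 1070 genes had an unadjusted p under 0.05 where 1093 would be expected by chance. With slide as a block that count was 2421, above the 1093, so the unblocked count does not show a lack of effect. Among those that did not pass, Cyp2b9 differed by -2.89 ± 0.65 (adjusted p = 0.273), Cyp2b13 by -2.78 ± 0.59 (adjusted p = 0.217), Aatk, a kinase gene, by -1.25 ± 0.22 (adjusted p = 0.0519), Slc2a2, the gene of the glucose transporter GLUT2, by -1.12 ± 0.27 (adjusted p = 0.441), and Pparg by -0.61 ± 0.19 (adjusted p = 0.743). Sirt1, which encodes a deacetylase often studied with resveratrol, differed by 0.29, and Cyp4a14, a PPARalpha target, by 1.29. Differences within the 4 slides that held both groups were -3.16 to -2.30 for Hao2 and -2.52 to -0.68 for Olfr701. Those of Hao2 are not exact, because it was well above background in 0 of 6 HR livers. The adjusted p of Olfr701 was 0.135 with slide as a block, and normexp background correction ended the call of Hao2 (log2 difference -0.21, adjusted p = 0.729). Leaving out any 1 HFD array, or HR replicate 1, 3, 4 or 5, ended the call of Olfr701, which was kept in 9 of 29 alternatives, and normexp brought its difference to -0.46 (adjusted p = 0.598).

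In HR against HFD camera called 12 of 33 lists. Markers of sinusoidal endothelium were called higher, with 14 of 14 above 0, a median of 0.56, and 2 members that rose when adjusted over the list alone: Clec4g (0.83), a lectin gene, and Bmp2 (0.77), which encodes a signal for hepatocyte iron sensing (adjusted p = 0.0717 with an estimated correlation). Kupffer cell markers were called higher with 10 of 10 above 0 and a median of 0.53 (adjusted p = 0.0717 with an estimated correlation). P450 genes of drug metabolism were called lower, with 26 of 33 below 0, a median of -0.27 and 3 members that fell when adjusted over the list alone (adjusted p = 0.0717 with an estimated correlation). Female-biased genes were called lower, with 15 of 23 below 0 and a median of -0.34 (adjusted p = 0.0717 with an estimated correlation). Hao2 fell over all genes, and when adjusted over the list alone 5 members fell, among them Ntrk2, which was well above background in 0 of 6 HR livers, and Cux2 rose (0.90). Genes of the circadian clock were called lower with 16 of 19 below 0 and a median of -0.50, such as Ciart (-1.81) and Bhlhe40 (-0.98), which encode repressors of the clock, and the adjusted p = 0.106 with an estimated correlation. PPARalpha targets were called higher with a median of 0.26 (adjusted p = 0.670 with an estimated correlation), macrophage genes with 0.25 (adjusted p = 0.574 with an estimated correlation) and genes of stellate cells and matrix with 0.12 (adjusted p = 0.580 with an estimated correlation). Lower medians were called for glucose metabolism at -0.18 (adjusted p = 0.423 with an estimated correlation), fatty acid synthesis at -0.14 and male-biased genes at -0.29 (adjusted p = 0.574 with an estimated correlation for both), and oxidative phosphorylation at -0.11 (adjusted p = 0.921 with an estimated correlation). The calls of PPARalpha targets (adjusted p = 0.684), male-biased genes (0.226), macrophage genes (0.0635) and genes of stellate cells and matrix (0.170) were lost with slide as a block. As many lists were called in 50 of 100 splits of the arrays.

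The mixture of both compounds, HQR, was also compared with HFD. No gene passed limma's adjusted p of 0.05, and 297 genes had an unadjusted p under 0.05 where 1093 would be expected by chance. As for HQ, the lack of calls does not show a lack of effect. The smallest adjusted p, 0.0634, again belonged to Hao2, at -5.32 ± 0.88 (SD, n = 6) in HQR, with 1 of 6 HQR livers well above background, so that no exact difference is given. With slide as a block, 2 genes passed, Hao2 among them (adjusted p = 0.0214), and 558 genes had an unadjusted p under 0.05. Cyp2b13 differed by -3.19 ± 0.59 (adjusted p = 0.110) and Cyp2b9 by -3.17 ± 0.65 (adjusted p = 0.157), in 6 of 6 HQR livers. Cidea differed by -2.57 ± 0.77 and Cidec by -1.45 ± 0.56 (adjusted p = 0.987 for both). Differences within the 4 slides that held both groups were -2.66 to -0.92 for Hao2, -4.28 to -1.87 for Cyp2b13 and -3.73 to -2.81 for Cyp2b9. Those of Hao2 are not exact either. Normexp background correction brought Hao2 to -0.36 (adjusted p = 0.981). Without HQR replicate 4, 4 genes passed, and without HFD replicate 2, 1 gene did.

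Camera called 14 of 33 lists in HQR against HFD, and 2 of these calls held with an estimated correlation. These 2 lists share members, the Cyp2b genes among them, so they are not separate results. The P450 list was not tested without its Cyp2b genes. Female-biased genes were lower, with 17 of 23 below 0 and a median of -0.56 (adjusted p = 0.000911 with an estimated correlation, and 0.00979 by fry). None passed over all genes, and 5 fell when adjusted over the list alone: Cyp2b13, Cyp2b9, Cyp2b10, Hao2 and Ntrk2, which encodes a neurotrophin receptor. Cyp2b10, like Hao2, was well above background in 1 of 6 HQR livers and Ntrk2 in 0 of 6, so no exact difference is given for them. P450 genes of drug metabolism were lower, with 29 of 33 below 0 and a median of -0.28 (adjusted p = 0.00816 with an estimated correlation, and 0.0543 by fry), and 4 fell when adjusted over the list alone, namely the 3 Cyp2b genes and Cyp2c38 (-1.44). The medians within slides ran from -0.91 to 0.12 for the female-biased list and from -0.57 to 0.18 for the P450 list. The other 12 calls were lost with an estimated correlation. Clock genes had a median of -0.44 (adjusted p = 0.0677 with an estimated correlation), lipid droplet genes -0.17 (0.443), glucuronidation and sulfation genes -0.10 (0.476), interferon response genes -0.11 (0.515), glucose metabolism -0.12 (0.524), lipoproteins -0.15 (0.581), oxidative phosphorylation -0.21 with 46 of 50 below 0 (0.581), and ribosomal proteins -0.19 with 46 of 52 below 0 (0.694). Higher medians were called for cholangiocyte markers, at 0.22 with 14 of 14 above 0 (adjusted p = 0.206 with an estimated correlation), Kupffer cell markers at 0.29 (0.515), sinusoidal endothelium at 0.26 (0.524) and cholesterol synthesis and uptake at 0.34 with 18 of 23 above 0 (0.638). Slide as a block ended the calls of cholesterol synthesis and uptake (adjusted p = 0.155), lipoproteins (0.399), glucose metabolism (0.214) and glucuronidation and sulfation (0.189). As many lists were called in 31 of 100 splits of the arrays.

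**Figure D3:**
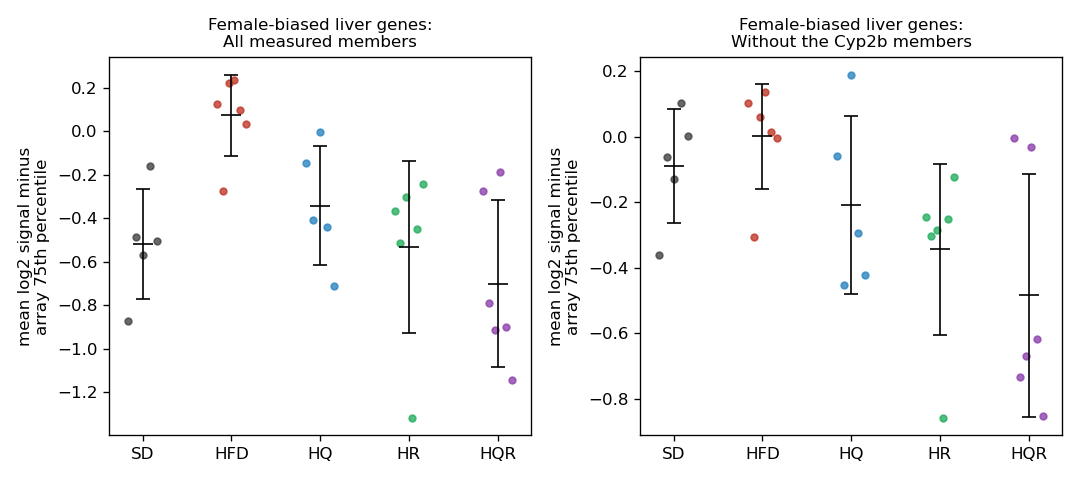
Mean log2 signal relative to the array's 75th percentile over the female-biased list, for all 23 measured members and for the 20 without Cyp2b genes, in each of the 28 livers by diet group; each point is 1 array. The mean over all 23 members differed from HFD by -0.77 in HQR.

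Quercetin and resveratrol were compared at the same dose of 0.4% and the same time. No gene passed limma's adjusted p of 0.05 in HQ against HR, and 283 genes had an unadjusted p under 0.05 where 1093 would be expected by chance. The difference of HQ from HR, with its interval of 2 SE either way, was 1.39 (0.02 to 2.75) for Cyp2b9, 1.43 (-0.18 to 3.03) for Cidea, 0.31 (-0.84 to 1.47) for Cfd and -0.03 (-0.56 to 0.50) for Sirt1. It was 0.01 (-0.88 to 0.90) for Cyp1a1, the classic target of the aryl hydrocarbon receptor. The intervals of Cyp2b9, Cidea and Cfd leave room for differences of more than 1 on the log2 scale. Hao2 was not well above background in any HQ or HR liver, so its levels in the 2 groups cannot be compared. Moxd1 had an interval of 1.05 to 4.24 around 2.65 and Grin3b one of 0.64 to 1.75 around 1.19, but their adjusted p was 1.00, and Moxd1 was well above background in 3 of 6 HR livers. Camera called 13 lists, among them Kupffer cell markers, lower in HQ with 10 of 10 below 0 and a median of -0.33 (adjusted p = 0.313 with an estimated correlation), and interferon response genes, higher with a median of 0.24 (adjusted p = 0.314 with an estimated correlation). None of the 13 calls held with an estimated correlation, and 8 held with slide as a block, that of interferon response genes (adjusted p = 0.263) not among them.

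The mixture held each compound at 0.2%, so its doses differ from the single 0.4% diets. No gene passed limma's adjusted p of 0.05 in HQR against the mean of HQ and HR (494 genes with an unadjusted p under 0.05), against HQ (306) or against HR (605). In each of these, 1093 genes would be expected by chance. Grin3b, which encodes a glutamate receptor subunit, differed by -1.44 ± 0.28 between HQR and HQ (adjusted p = 0.400). Interferon response genes were lower in HQR than in HQ, with 25 of 28 below 0 and a median of -0.41 (adjusted p = 0.00313 with an estimated correlation, 0.0612 by fry). With slide as a block their median was -0.23 and their adjusted p 0.000792 by camera with the preset correlation. They were lower than the mean of HQ and HR, with 26 of 28 below 0 and a median of -0.32 (adjusted p = 0.0271 with an estimated correlation, 0.182 by fry). No member passed over all genes or when adjusted over the list alone. The remaining calls in these 3 comparisons, 11, 9 and 13 of 33 lists, were lost with an estimated correlation, 4 of 12, 4 of 10 and 3 of 13 calls held with slide as a block, and as many lists as in HQR against HQ were called in 36 of 100 splits.

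Each supplemented group was also set against the standard diet. Cfd rose in HQ by 4.27 ± 0.60 (adjusted p = 0.00342), in HR by 3.95 ± 0.58 (adjusted p = 0.00319) and in HQR by 4.09 ± 0.58 (adjusted p = 0.00255), and H2-Q1, a class I histocompatibility gene, fell in each by 1.73, 1.90 and 1.77. Enho fell by 1.36, 1.38 and 1.70. Cidea (5.06), Cidec (3.25) and Cyp2b9 (4.46) rose in HQ, Tff3 fell in HR (-1.76) and HQR (-1.81), Moxd1 fell in HR (-4.25), and Asns fell in HQR (-2.72, adjusted p = 0.0406). The value of Moxd1 is not exact, because 3 of 6 HR livers were well above background. In all, 8 genes passed in HQ (6 rose and 2 fell), 12 in HR (7 and 5) and 14 in HQR (6 and 8), and 13, 31 and 48 with slide as a block, of which 4, 9 and 12 were shared. The calls lost with slide as a block include Cyp2b9 (adjusted p = 0.0725), Cidec (0.0722), Enho (0.207) and Drc7 (0.0768) in HQ, and Enho (0.0715) and Moxd1 (0.120) in HR. Leaving out 1 array gave 1 to 10 genes in HQ, 2 to 12 in HR and 7 to 25 in HQR. Drc7, an axonemal gene that was singled out after its values were seen, rose in HQ (1.30, a call lost with slide as a block), HR (1.45) and HQR (1.19). Of the 25 genes that differed between HFD and SD, 7, 6 and 6 also differed the same way between SD and HQ, HR and HQR, but the SD arrays enter both sides. With these arrays split between the sides, over 20 splits, a mean of 0.9, 0.7 and 0.75 genes was shared, at most 4, 3 and 3, from fewer calls. Independent lists would share 0.00503, 0.00709 and 0.00778, which leaves out the shared arrays. Simulated unchanged groups shared 0, 0.02 and 0.01, but they hold no diet effect and called genes in HFD vs SD in 1 of 100 simulations, so neither value is a reference for the observed overlaps. Genes of cholesterol synthesis and uptake were below 0 in 23 of 23 cases in HQ (median -0.49), 22 of 23 in HR (-0.55) and 15 of 23 in HQR (-0.27), and were called lower in each, with adjusted p = 0.285, 0.302 and 0.573 with an estimated correlation.

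The last question was whether the compounds moved the liver back toward the standard diet. The 2 genes that fell in HR against HFD, Hao2 and Olfr701, had both risen in HFD against SD, although with slide as a block Olfr701 passed in neither comparison, and the HFD arrays enter the 2 comparisons with opposite sign. With these arrays split between the sides, a mean of 0.35 genes was shared over 20 splits, and 1 at most. Independent lists would share 0.00137, which leaves out the shared arrays, and simulated unchanged groups, which hold no diet effect, shared 0, so neither value is a reference for the 2 genes. Of the 25 diet genes, 23 (92%) were closer to SD in HQ, 24 (96%) in HR and 22 (88%) in HQR, and the median share of the diet difference left was 73.1%, 63.3% and 61.7%. It was 74.5%, 65.8% and 62.3% over the 22 genes that most HFD and most SD arrays measured well above background. For Cyp2b9 that share was 74.8%, 51.6% and 46.8%, for Cfd 78.4%, 72.6% and 75.2%, for Cidea 86.5%, 62.1% and 56.0% and for Asns 59.7%, 76.1% and 86.1%. Genes picked for a large HFD value lie closer to SD in any other group, so groups without a compound effect were simulated from the residuals. With diet effects placed in all genes, 73.9%, 72.5% and 73.5% of the diet genes were closer to SD, at most 93.3%, 95.1% and 96.1%, so that the share in HR lay above the highest simulated one and those in HQ and HQR did not, and 84.1%, 86.2% and 85.3% of the difference was left, at least 58.6%, 60.7% and 37.1%. These simulations held a mean of 219 diet genes against the 25 observed, and the version below 11.2, so the shares rest on different numbers of genes. With effects placed in the called genes alone, a version chosen after the first had been seen and against which the observed values look more unusual, 56.4%, 56.7% and 54.9% were closer, at most 100%, and 97.8%, 98.0% and 97.8% was left, at least 73.0%, 82.8% and 73.6%. Across genes, which are not independent replicates, the correlation of the diet difference with the compound difference was -0.05 for HQ, -0.04 for HR and 0.01 for HQR when the shared HFD arrays were split between the 2 sides. Between compounds it was 0.02 for HQ and HR, -0.04 for HQ and HQR and -0.03 for HR and HQR. The low and high values in simulated unchanged groups were -0.50 and 0.39 for HQ, -0.51 and 0.48 for HR, and -0.41 and 0.49 for HQR. Between compounds they were -0.47 and 0.51, -0.45 and 0.62, and -0.41 and 0.47. With such wide limits, values near 0 show neither a reversal or agreement nor a lack of it. With the HFD arrays on both sides the 6 correlations were -0.56, -0.51, -0.45, 0.63, 0.53 and 0.51, and simulated unchanged groups gave means of -0.45, -0.38, -0.44, 0.42, 0.45 and 0.44. Their low values were -0.83, -0.81, -0.83, -0.28, -0.23 and -0.22, and their high values 0.05, 0.10, 0.23, 0.83, 0.86 and 0.80. The observed correlations lie inside these limits. The unsplit covariances differed from the simulated ones by -0.0101, -0.0213, -0.00507, 0.00767, -0.00808 and 0.00203.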

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

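The test of outlying arrays was a fixed one, and no explanation was tested for the array it marked. Of 14 measures, namely the genes with the largest changes past the threshold and the signal and background measures of each array, in 5 groups (70 sets in all), 1 set held an array far from the others, and by chance about 5% of such sets hold one. Hao2 was -3.55 in HQR replicate 4, while the nearest HQR array was at -5.50 and the lowest at -5.91, so that the gap made up 0.826 of the group's range. That array lies on slide 8. It was the 1 HQR array on which Hao2 was well above background, and without it Hao2 passed the threshold between HQR and HFD (fitted difference -2.56, which is no exact value because no HQR array was then well above background).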

How the results depend on the processing

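Alternatives added after the data had been seen were slide as a random block, quantile normalization with slide as a block, leaving out slide 8, and the 2 pooled contrasts; the others were planned. Where a count moved, the cause was not tested. Counts of genes passing are given against the reported 25 (HFD vs SD), 0 (HQ vs HFD), 2 (HR vs HFD), 0 (HQR vs HFD), 8 (HQ vs SD), 12 (HR vs SD) and 14 (HQR vs SD), and those that stayed within 1.5 times are left out. Quantile normalization gave 1 for HQ vs HFD and 3 for HQR vs HFD. Scaling to the array median gave 1, 1 and 3 for HQ, HR and HQR vs HFD and 4, 5 and 9 for HQ, HR and HQR vs SD. Normexp gave 4 for HR vs HFD (0 shared with the reported 2), 2 for HQR vs HFD, 4, 1 and 6 for HQ, HR and HQR vs SD, and a correlation of 0.667 between the HQ and HR differences. No filter gave 1 for HR vs HFD, and the strict filter 4 for HR vs HFD, 1 for HQR vs HFD and 23 for HQR vs SD. The deposited value table gave 1, 1 and 3 for HQ, HR and HQR vs HFD and 14 for HQ vs SD. The mean of all probes gave 4 for HR vs HFD and 2 for HQR vs HFD. The compared arrays alone gave 10 for HFD vs SD, 1 for HR vs HFD, 2 for HQR vs HFD, and 0, 0 and 7 for HQ, HR and HQR vs SD. The robust trend gave 4 for HR vs HFD and 25 for HQR vs SD. Array weights gave 40 for HFD vs SD, 1 for HQ vs HFD, 6 for HQR vs HFD, 1 for HQR vs the mean of HQ and HR, 1 for HQR vs HR and 107 for HQR vs SD. Slide as a block gave 1 for HR vs HFD, 2 for HQR vs HFD, and 13, 31 and 48 for HQ, HR and HQR vs SD, and scan day as a block 1 for HR vs HFD. Slide as a random block gave 76 for HFD vs SD, 1, 8 and 9 for HQ, HR and HQR vs HFD, and 14, 49 and 101 for HQ, HR and HQR vs SD. Quantile normalization with slide as a block gave 1 for HR vs HFD, 2 for HQR vs HFD, and 14, 29 and 61 for HQ, HR and HQR vs SD. Without slide 8 there were 1 for HQ vs HFD, 2 for HQR vs HFD, and 4, 5 and 8 for HQ, HR and HQR vs SD. With the shared HFD arrays on both sides, the correlations of the diet difference with HQ and HR were -0.564 and -0.512, and those between compounds 0.627, 0.529 and 0.507, as the shared arrays by construction pull them away from 0.

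Leaving out 1 array gave 15 to 27 genes for HFD vs SD (15 without HFD replicate 3), 0 to 1 for HQ vs HFD (1 without HFD replicate 2, HQ replicate 1 or 4), 1 to 3 for HR vs HFD (1 without HFD replicate 1, 2, 3, 4 or 6 or HR replicate 1, 3, 4 or 5), and 0 to 4 for HQR vs HFD (1 without HFD replicate 2, 4 without HQR replicate 4). It gave 1 to 10 for HQ vs SD (3 or fewer without SD replicate 1, 4 or 5 or HQ replicate 1, 3 or 4), 2 to 12 for HR vs SD (2 without SD replicate 4 or 5, 5 without HR replicate 6) and 7 to 25 for HQR vs SD (25 without SD replicate 1, 9 or fewer without SD replicate 3, 4 or 5 or HQR replicate 3 or 4). Outside HFD vs SD the replicate numbers do not pair the livers (correlations of -0.469 to 0.695). In HFD vs SD, 3 of 5 arrays correlate best with their own number. Replicate number as a block ended 3 list calls in HFD vs SD, changed no other call of a named gene or list there, and gave 33, 0, 2, 0, 0, 0, 0, 0, 7, 12 and 14 genes, in the order HFD vs SD, HQ, HR and HQR vs HFD, HQ vs HR, HQR vs the mean, vs HQ and vs HR, and HQ, HR and HQR vs SD. Normexp shifted the median of all genes to -0.15 for HFD vs SD, 0.25 for HQ vs HFD, 0.18 for HR vs HFD, 0.12 for HQ vs HR, -0.14 for HQR vs the mean, -0.17 for HQR vs HQ and 0.19 for HQ vs SD. The share of changed genes that rose was 58.3% for HR vs SD (7 rose and 5 fell), 40% with the array median (2 and 3) and 100% with normexp (1 and 0). For HQR vs SD it was 42.9% (6 and 8), 65% with quantile normalization (13 and 7) and 57.1% with the value table (8 and 6). For HQ vs SD it was 75% (6 and 2) and 100% with normexp (4 and 0). So few genes show no change in direction.

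Camera's direction turned for 4 lists, with these medians: PPARalpha targets in HR vs HFD with normexp (-0.000154), acute phase genes in HFD vs SD without SD replicate 4 (0.0685, range over left-out arrays -0.597 to 0.0685), and oxidative phosphorylation in HR vs HFD without HFD replicate 3 (-0.000557, range -0.212 to -0.000557) and in HQ vs HFD without HQ replicate 2 (0.0844, range -0.351 to 0.0844). Other list medians crossed 0 while camera kept its direction. In HFD vs SD these were lipoproteins (0.0866 with quantile normalization), female-biased genes (0.0588 without SD replicate 3), lipid droplet genes (-0.0652 with array weights) and cell cycle genes (-0.0272 with normexp), besides female-biased genes in HQ vs HFD (0.103 with normexp) and lipoproteins in HQR vs HFD (0.00249 with the value table). No named gene changed sign where either value passed, but without a pass 7 of 49 did in HFD vs SD and 18 of 52, 7 of 64 and 8 of 67 in HQ, HR and HQR vs HFD, such as Hao2 (0.18) and Cyp2b10 (0.28) in HQ vs HFD and Cyp2b10 (0.04) in HR vs HFD with normexp. For named genes, 28 values lost and 14 gained the threshold in HFD vs SD, 0 and 9 in HQ vs HFD, 21 and 20 in HR vs HFD and 0 and 29 in HQR vs HFD. In the same order, list calls were lost in 56, 47, 89 and 69 combinations of a list and a setting. The 4 in which camera's direction turned lost the call as well and are not among these. Cfd, Cidea, Cyp2b9 and Cyp2b13 passed in HFD vs SD in all 28 alternatives run for them. Where a group lay under background, as Hao2 in SD and HR, the difference is not exact.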

Other observations

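The contrasts of pooled groups, the slide and Cyp2b tests, the adipocyte test, the second Y-linked test and both tests of ATF4 targets were chosen after the results they bear on had been seen. The splits of arrays, except those that part pairs, and the first Y-linked test were not. Against SD, the 4 high fat groups together (23 livers) had 38 changed genes, of which 18 rose and 20 fell, and 112 with slide as a block, 31 of them shared. Beyond the genes already described, Cyp8b1, which encodes the sterol 12-hydroxylase of bile acid synthesis, fell by 1.42 ± 0.31 (adjusted p = 0.0491, and 0.0739 with slide as a block), Sqle fell by 1.59 ± 0.33 (adjusted p = 0.0443) and Cyp2c54 fell by 1.21 ± 0.24 (adjusted p = 0.0341). Against HFD, the 3 supplemented groups together had 1 changed gene, Hao2, which fell (adjusted p = 0.000493) and was well above background in 0 of 5 HQ, 0 of 6 HR and 1 of 6 HQR livers, so that no exact difference is given. Their P450 genes of drug metabolism were lower, with 31 of 33 below 0 and a median of -0.32 (adjusted p = 0.0264 with an estimated correlation), as were female-biased genes, with 16 of 23 below 0 and a median of -0.42 (adjusted p = 0.0224 with an estimated correlation). Both lists hold the Cyp2b genes, so the 2 calls are not separate results. Markers of other cell types lay the other way without passing that test: 14 of 14 of sinusoidal endothelium were above 0 (median 0.41, adjusted p = 0.156 with an estimated correlation), as were 9 of 10 of Kupffer cells (median 0.34, adjusted p = 0.344 with an estimated correlation).

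Cfd and the lipid droplet genes Cidea and Cidec were higher in HFD than in SD livers. Adipose tissue in the samples would raise its other markers too, but the adipocyte list without Cfd had a median of -0.372, no member's upper bound was above 0.849, and Adipoq differed by -1.04 and Fabp4 by 0.09. Slide batches would take up the difference, but with slide as a block 109.6% ± 11.2 (SE) of the mean difference of Cfd, Cidea and Cidec was kept. As a hypothesis found and tested on the same livers, the rise may be an effect of the diet on liver cells. A change of cell composition other than adipocytes was not tested.

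Camera with the preset correlation called female-biased genes lower than in HFD in each supplemented group. With an estimated correlation that call held in HQR and in the pooled contrast, but not in HQ or HR. The same HFD arrays enter all of these contrasts, so the calls are not independent of each other. Cyp2b9, Cyp2b13 and Hao2 had also been called higher in these HFD arrays against SD. Genes picked for a large HFD value lie closer to SD in any other group, and that share of the fall was not tested. Female livers among the HFD arrays would lack Y-linked signal: most of 7 Y-linked probes were not well above background on 1 of 28 arrays, which met the mark set beforehand for such livers, but it was an HR array, 0 HFD arrays were affected, and the brightest probes of Ddx3y, Kdm5d and Eif2s3y, tested next, failed on 0 arrays. With slide as a block the mean of the list was still below HFD in HQR, HR and HQ, with differences of -0.768 ± 0.200 (SE), -0.641 ± 0.200 and -0.565 ± 0.235. Without its Cyp2b genes, whose probes could share signal, the differences were -0.486 ± 0.151, -0.345 ± 0.151 and -0.209 ± 0.158, so that shared signal stays open for HQ, whose difference lies within 2 SE of 0. The 20 genes left include Hao2 and Ntrk2, with fitted differences of -2.20 and -3.00 in HQR and -2.74 and -2.37 in HR. These were well above background in 1 of 6 and 0 of 6 HQR livers and in 0 of 6 HR livers each. The means without Cyp2b genes are therefore not exact, and a fall spread over the whole list was not tested. A change limited to these genes and a change of cell composition stay open and were not tested, as does a general shift toward the male pattern, since male-biased genes had medians of 0.03 in HQ, -0.29 in HR and 0.10 in HQR but within slides of 0.12 to 0.56, -0.04 to 0.23 and -0.000549 to 0.43, and as many lists as in HQR against HFD were called in 31 of 100 splits.

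Asns was lower in the high fat groups than in SD (-2.54 ± 0.42, adjusted p = 0.00442). If it followed a lower activity of the stress factor ATF4, other ATF4 targets would be lower too, and 17 of 23 measured targets were below 0, with a median of -0.28 and 0 called (camera p = 0.0636 with an estimated correlation). Chac1 (1.30) and Vldlr (0.95) went the other way, with slide as a block 2 targets passed in opposite directions, Trib3 (-1.11, adjusted p = 0.0231) and Chac1 (1.49, adjusted p = 0.0412), and a first run without Chac1, which has a missing value on 1 array, had given a p of 0.0249; Chac1 was put back after that p had been seen. The list itself was written after Asns, Slc1a5 and Vldlr had been seen. A p of 0.05 or more had been written down as evidence against ATF4, but it was judged after the value was seen that a missed threshold excludes nothing, so ATF4 was neither found nor excluded as the cause.

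Splits of the same arrays into groups of the same sizes, 100 per comparison with the real one included, gave the following. As many genes as the 25 of HFD vs SD were called in 3 splits, as many as the 2 of HR vs HFD in 2, as many as the 8, 12 and 14 of HQ, HR and HQR vs SD in 3, 1 and 1, and as many as the 38 of the pooled high fat groups in 4. These lie under the mark of 5 splits of 100, and the 1 gene of the pooled supplemented groups does not (7 splits). Chance is not excluded by this. So few splits give the shares coarsely, nothing was adjusted over the comparisons, and the splits took no account of the slides. For the counts of 0 in HQ and HQR vs HFD, HQ vs HR, and HQR vs the mean, vs HQ and vs HR, all 100 splits reach 0 by construction, so they say nothing about chance. The highest count of another split was 6661 for HFD vs SD, 2592 for HR vs HFD, 4217, 2 and 2 for HQ, HR and HQR vs SD, 3926 and 7327 for the pooled contrasts, 10 and 4219 for HQ and HQR vs HFD, and 3, 2, 0 and 1 for the comparisons among supplemented groups. Splits with such high counts point to a structure of the samples, but slide was not shown to be its source: slide explained a share of 0.817 of the split with 6661 genes, 1.00 of those with 2592 and 4217, 0.778 of that with 4219, 0.148 of that with 3926 and 0.399 of that with 7327, and a share as large in 28, 5, 20, 17, 93 and 43 of the other 99 splits. In HFD vs SD, where replicate numbers were taken to pair the livers, 32 splits part all 5 pairs, and of these only the real one called 25 genes and the highest other 1, so the high counts came from splits that leave pairs together. The pairs were read from these same arrays and not from the labels, and 3 of 5 correlated best with their own number. This smaller set of splits is therefore no independent test against chance. With slide as a block, 33 genes passed in HFD vs SD, 1 in HR vs HFD and 13 in HQ vs SD.

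For the lists called by camera with the preset correlation, chance cannot be excluded in any comparison. As many as the 6, 8, 12 and 14 lists of HFD vs SD and of HQ, HR and HQR vs HFD were called in 89, 83, 50 and 31 splits (highest 21, 23, 22 and 19). As many as the 13, 12, 10 and 13 of HQ vs HR and of HQR vs the mean, vs HQ and vs HR were called in 35, 23, 36 and 16 (highest 21, 18, 16 and 16). As many as the 14, 16 and 15 of HQ, HR and HQR vs SD were called in 31, 13 and 12 (highest 21, 19 and 20), and as many as the 12 and 12 of the pooled high fat and pooled supplemented contrasts in 44 and 31 (highest 22 and 20).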
